A study of Mus musculus with 12 samples.

How the data were processed

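RNA from bone marrow erythroblast fractions of C57BL/6 mice was measured on 12 MTA-1_0 gene expression arrays, 3 for each of the WT, Bhet, mKO and mKO/Bhet genotypes, from 250 ng of RNA per array. The deposited values are log2 signals per probe set, normalized across arrays by the authors with RMA, as the submitters' processing notes state. The signals are labelled sst-rma-gene-full. Neither the software version nor what the sst step does to the size of changes is given in the sources used here. Both deposited tables held 72688 probe sets and the same values (largest difference 0.0), and no column of another sample. The signals of 89 genes kept a fixed distance from each array's highest value over several arrays and were taken as saturated. Their limit was not the same: on WT replicate 2 Hba-a1 stood at 19.93 and Hbb-bs at 17.815. For arrays there is no read depth, and the number of arrays limits the precision.

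From the 72688 probe sets, 6920 control and normalization probe sets were left out, which left 65768 transcript clusters. A symbol was assigned to 31336 of them, 21049 through a RefSeq accession, and the 34432 without a symbol were tested only as single clusters. Where several clusters had the same symbol, as for 246 genes, the cluster with the highest mean was taken, which gave 30978 genes. Positions are on GRCm38: 27090 of 27301 genes, or 99.2%, overlapped the gene of the same symbol in that annotation. No gene had a cross-hybridization mark (0), and 2 symbols had been turned into dates, as spreadsheets do. The region of miR-144 and miR-451 was taken by coordinates, since its probe set had no symbol.

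A cell-means model with all 12 arrays was fitted with limma (version 3.58.1, R version 4.3.3), with empirical Bayes moderation and a mean-variance trend (8 residual and 3.45 prior degrees of freedom). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes within each of 8 contrasts at a threshold of 0.05. Gene lists, 27 with at least 3 measured genes, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry. The contrasts, tests, lists, other settings and the rule for named genes were fixed before the data were examined. Region signals were compared with exact permutation tests. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

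The rule named, per comparison, the 10 genes with the largest change in each direction among those past the threshold whose groups did not overlap, or 5 in each direction for the interaction and the averages. Where fewer than 5 genes passed, it named the 5 with the smallest p in each direction, and it left predicted and unannotated genes out of the names (10967 symbols). In each list described it named the 2 to 4 members with the smallest p, and it always named the globins, the microRNAs and a set of known targets and iron, heme and autophagy genes. Not every gene that the rule names is reported here.

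Settings varied were the 15489 genes of highest mean alone, the mean of a gene's clusters, each cluster on its own, no mean-variance trend, only the groups compared, array weights, a further quantile normalization, centring each array on its median, the replicate number as a block, and each array left out in turn. Covariates for Y-linked and for late erythroid signal, the lists without saturated members, the background limit (the highest antigenomic value of each array), the joint removal of WT replicate 1 and mKO/Bhet replicate 3, and the removal of arrays of groups not compared were added after seeing the data. The test was also run on simulated data with 30978 genes, 200 of them changed: it recovered 67.5%, 92.2% and 99.4% of genes shifted by 1, 2 and 4 on the log2 scale, with 4.93% of calls false, and made 0 calls where nothing changed. The simulated noise was independent between genes. These shares need not hold for the real arrays, where another split of the mKO and WT arrays gave 70 genes.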

Results

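Gene expression was measured in erythroblast fractions, the red cell precursors, taken from the bone marrow of C57BL/6 mice of 4 genotypes. The groups were WT, Bhet, mKO and mKO/Bhet, with 3 arrays per group, each from a mouse numbered within its group. Bhet is read here as the th3 heterozygous genotype named in the design text, a β-globin deletion that gives mice a β-thalassemia, and mKO as loss of the locus of miR-144 and miR-451 named in the series title. The files held 12 arrays, and 30978 genes with a symbol were tested. Median log2 signals per array ran from 3.73 to 4.22, and the precision of each mean was limited by the 3 arrays behind it.

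Red cell genes and white cell genes were both abundant on these arrays. Slc4a1, the band 3 anion exchanger of the red cell membrane, had a mean log2 signal of 17.57 ± 1.22 (SD, n = 3) in WT, 18.97 ± 0.08 in Bhet, 16.92 ± 1.26 in mKO and 18.68 ± 0.48 in mKO/Bhet. Ltf, the lactoferrin of neutrophil granules, had 19.69 ± 0.06 in WT, 19.49 ± 0.02 in Bhet, 19.77 ± 0.10 in mKO and 18.64 ± 0.89 in mKO/Bhet. The adult globins Hba-a1, Hbb-bt and Hbb-bs were saturated, as were 89 genes in all, so no fold change is given for them. The highest antigenomic background value of an array lay between 4.77 and 6.81, and a gene at or below it on every array of a group has an uncertain level there. The mKO/Bhet replicate 3 array stood apart, with a median of 4.22, a highest value of 19.55, a mean correlation of 0.960 with the other arrays, and an exon over intron control AUC of 0.777, where the others had 0.832 to 0.864. Each WT array correlated best with an array of another group, and WT replicate 1 was the furthest from its own group, at 0.991 with mKO/Bhet replicate 2 against 0.979 and 0.984 with the other WT arrays. Y-linked genes gave high signal on all WT arrays, on Bhet replicate 2 and on mKO replicates 1 and 2, and low signal on all mKO/Bhet arrays, so sex differed between and within groups.

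**Figure D1:**
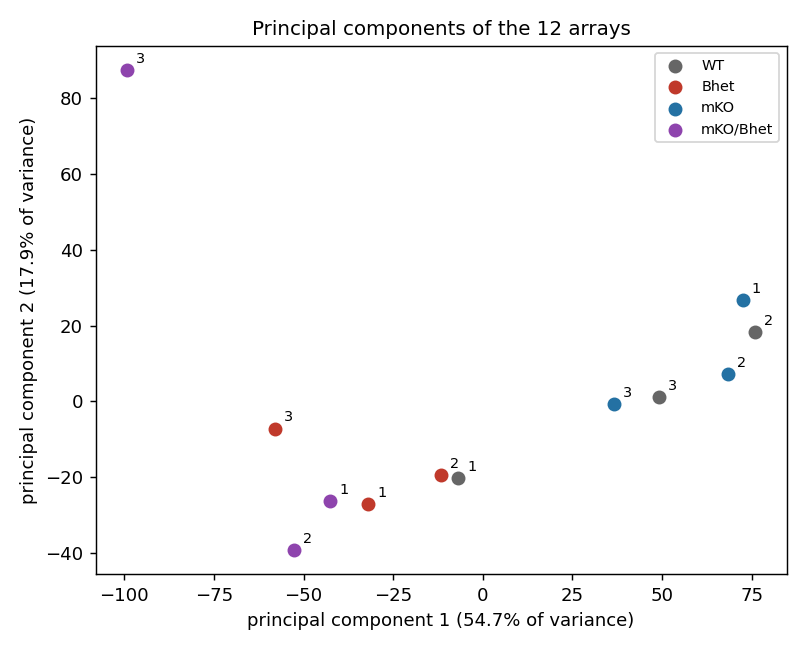
Each point is an array, placed by its principal component 1 (54.7% of variance) and principal component 2 (17.9% of variance) over all tested genes, in arbitrary units, coloured by group and numbered by replicate. On component 1 the Bhet and mKO/Bhet arrays lie at negative values, as does WT replicate 1 at -6.78, beside Bhet replicate 2 at -11.6, and mKO/Bhet replicate 3 lies apart on component 2 at 87.5.

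The locus of the microRNAs was examined first. The extent of the deletion is not given in the sources used here, so it is not known whether the probe set below lies inside it. This probe set, at chromosome 11, positions 78072649 to 78073517 (GRCm38), spans Mir144 and Mir451a and carries no gene symbol, so it was found by position. Its mean log2 signal was 8.97 ± 1.13 (SD, n = 3) in Bhet, 5.55 ± 0.36 in mKO/Bhet, 5.79 ± 0.63 in WT and 4.80 ± 0.36 in mKO. The log2 difference was -3.42 (SE 0.49) between mKO/Bhet and Bhet, with all mKO/Bhet arrays below all Bhet arrays (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Between mKO and WT it was -1.0 (SE 0.49, exact permutation p = 0.2), and the WT arrays overlapped the mKO arrays. Over the 6 arrays with the locus and the 6 without it, the exact permutation p was 0.0195. That test ignored the globin genotype and rests on Bhet, whose lowest array (7.80) lay above the highest WT array (6.35). The region separates the Bhet and mKO/Bhet labels but does not check the WT label, which limits every direction drawn from mKO and WT. The separate Mir451b probe set was dim, with a log2 difference of -0.88 (SE 0.21, adjusted p = 0.385) between mKO/Bhet and Bhet, and lay at or below background in both groups.

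**Figure D2:**
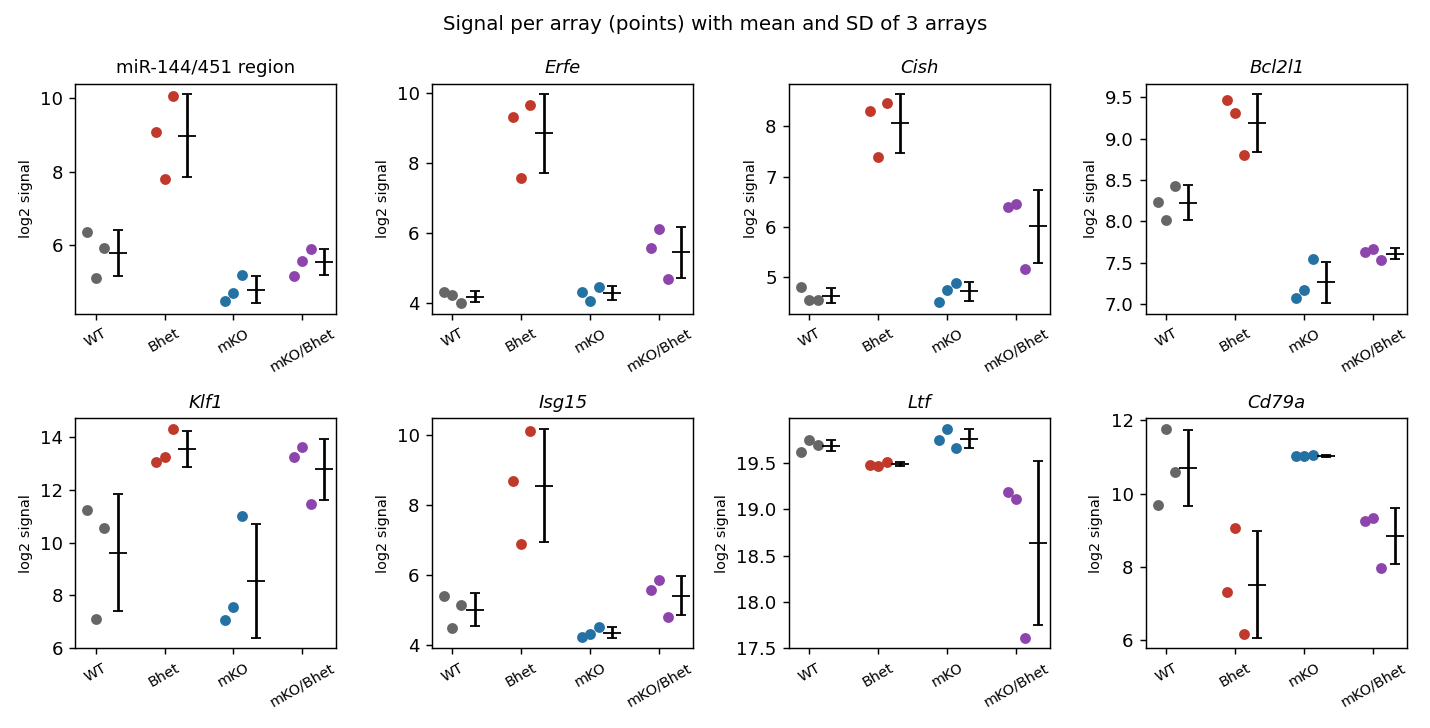
Log2 signal (vertical axes) of the region of miR-144 and miR-451 and 7 genes by group (horizontal axes), with a point per array and the mean and SD of 3 arrays as a line with bars. Erfe, Cish and Isg15 were highest on the 3 Bhet arrays, and Ltf stayed near the top of the scale in every group.

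The design text names the comparison of mKO/Bhet with Bhet, which asks what loss of the microRNAs does in thalassemic erythroblasts. Erfe (chromosome 1, 91366430 to 91374217), which encodes erythroferrone, the erythroblast hormone that suppresses hepcidin, had a mean log2 signal of 8.84 ± 1.12 (SD, n = 3) in Bhet and 5.45 ± 0.72 in mKO/Bhet, a log2 difference of -3.39 (SE 0.47). Slc2a4, the insulin-responsive glucose transporter on chromosome 11, differed by -2.46 (SE 0.34), the linker histone gene H1f3 by -1.48 (SE 0.20), Apold1 by -0.83 (SE 0.10) and Agrn by -0.78 (SE 0.10). On the other side, Tac2, a tachykinin gene, differed by 3.49 (SE 0.71), the ATP synthase subunit gene Atp5g2 by 2.19 (SE 0.37), the histone variant gene H2az2 by 2.05 (SE 0.33), Adam34l by 0.71 (SE 0.13) and Mex3d by 0.63 (SE 0.09). Adam34l lay at or below background in both groups and Mex3d in Bhet, so their differences are uncertain. None of these passed limma's test with Benjamini-Hochberg adjustment over 30978 genes, where 0 genes reached an adjusted p of 0.05, 11 lay under 0.10 (1 higher, 10 lower) and the lowest adjusted p was 0.0645. At an unadjusted p under 0.05 there were 2235 genes, against 1549 expected by chance, and the groups did not overlap for 10.4% of genes, where chance gives 10%. The count was 3973 with array weights, 5 (all higher) after another quantile normalization, and at most 3 with any array left out. Among the 15489 genes of highest mean alone it was 11, of which 1 was higher and 10 were lower. For replicates 1 to 3 the weights were 0.29, 0.94 and 5.27 in WT, 3.87, 0.78 and 0.38 in Bhet, and 2.95, 1.01 and 0.076 in mKO/Bhet. Counts with array weights thus rest largely on single arrays of these groups.

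Genes that respond to interferon were lower in mKO/Bhet than in Bhet, with all 22 members of the list below 0 and a median log2 difference of -1.43. Rsad2, an antiviral enzyme, differed by -3.67 (SE 0.68), Usp18, which removes Isg15 from proteins, by -3.64 (SE 1.20), the ubiquitin-like Isg15 by -3.15 (SE 0.62) and the RNA sensor Ifih1 by -1.37 (SE 0.41). No member passed over all genes, and 7 passed when adjusted over the list alone. The camera test with a preset correlation gave an adjusted p of 1.4e-15 for the list, and the adjusted p was 0.537 with an estimated correlation. Bhet replicate 3 carried much of the size, since without that array the median was -0.44, Usp18 differed by -1.76 and Ifih1 by -0.86.

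Genes of erythropoietin signalling did not pass. Bcl2l1, the survival factor of erythroblasts, differed by -1.58 (SE 0.23, adjusted p = 0.0691), Cish, a feedback inhibitor of the erythropoietin receptor, by -2.05 (SE 0.34, adjusted p = 0.146), the kinase gene Pim1 by -1.85 (SE 0.67) and the transcription factor gene Nfe2 by -0.97 (SE 0.31). Of the 19 measured members of the erythroid transcription and EPO signalling list, 14 were lower and 5 higher, with a median of -0.29, and 2 passed when adjusted over the list alone. The list passed with the preset correlation (adjusted p = 0.00025) and had an adjusted p of 0.537 with an estimated correlation. Its call ended without mKO/Bhet replicate 3 (median -0.057), after quantile normalization (median -0.037) and with the 15489 genes of highest mean alone (median -0.35). The median was -0.16 without Bhet replicate 2, -0.48 without mKO/Bhet replicate 1 and -0.45 without mKO/Bhet replicate 2. Pim1 differed by -0.92 and Nfe2 by -0.65 without mKO/Bhet replicate 3.

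Late erythroid and red cell membrane genes had a median log2 difference of -1.14, with all 24 members lower and none past the threshold. Trim10 differed by -2.51 (SE 0.77), the nuclear exportin gene Xpo7 by -1.89 (SE 0.58) and the adhesion gene Icam4 by -1.32 (SE 0.38). The list's adjusted p was 9.7e-10 with the preset correlation and 0.537 with an estimated correlation. Heme synthesis genes had a median of -0.56, with 11 of 15 lower and an adjusted p of 0.00904, or 0.554 with an estimated correlation. That call ended without mKO/Bhet replicate 3 (median -0.30), with the genes of highest mean alone, with centred arrays and after quantile normalization (-0.40).

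None of the stress genes passed over all genes. The inducible heat shock genes Hspa1a and Hspa1b differed by -2.57 (SE 0.48) and -1.94 (SE 0.41), and both passed when adjusted over the 13 measured heat shock and chaperone genes alone. That list had a median of -0.09 (adjusted p = 0.00885, or 0.554 with an estimated correlation), and its call ended without mKO/Bhet replicate 3 (median -0.012), with the genes of highest mean alone and after quantile normalization (-0.082). Its median was 0.0025 without Bhet replicate 1 and -0.24 without mKO/Bhet replicate 1, and Hspa1a lay at or below background in mKO/Bhet. Gadd45a, a growth arrest gene, differed by -1.09 (SE 0.22) and was the single member of the 19 FoxO3-associated genes to pass over its list alone, and Cat, the catalase gene, by -1.38 (SE 0.49). The FoxO3-associated list had 17 members lower and a median of -0.34 (adjusted p = 8.7e-05, or 0.537 with an estimated correlation), and its call ended without mKO/Bhet replicate 3 (median -0.12) and after quantile normalization (median -0.16). Ppp1r15a, the phosphatase subunit of the integrated stress response, differed by -2.06 (SE 0.43), and the ATF4 list of 23 genes had a median of -0.16 (adjusted p = 0.0092, or 0.537 with an estimated correlation). NRF2-associated genes had a median of -0.22 (adjusted p = 0.00403, or 0.554 with an estimated correlation). Iron handling genes, which include Erfe, had a median of -0.12 (adjusted p = 0.0143, or 0.554 with an estimated correlation). These 3 medians were -0.015, -0.071 and 0.025 without mKO/Bhet replicate 3, and none of the lists passed then. Their calls also ended after quantile normalization (-0.092, -0.15 and -0.11) and with the genes of highest mean alone, and that of iron handling with centred arrays. The NRF2 median was -0.14 without Bhet replicate 1.

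Of 27 lists 17 passed with the preset correlation, 16 lower and 1 higher. Without mKO/Bhet replicate 3 there were 6, of which 4 were higher, and after quantile normalization 6, of which 3 were higher. The 1 higher list was oxidative phosphorylation, with 23 of 28 members higher and a median log2 difference of 0.27 (adjusted p = 0.0242, or 0.671 with an estimated correlation). Sdhc, a subunit of succinate dehydrogenase, differed by 0.80 (SE 0.27) and Cox5a, a subunit of cytochrome c oxidase, by 0.56 (SE 0.28), neither past the threshold. The call ended without mKO/Bhet replicate 1 (median 0.18), mKO/Bhet replicate 2 (0.093) or Bhet replicate 2 (0.17). The median was 0.42 without Bhet replicate 3 and 0.52 without mKO/Bhet replicate 3. The autophagy list of 36 genes had a median of -0.16 (adjusted p = 0.0016, or 0.554 with an estimated correlation), which became -0.016 without mKO/Bhet replicate 3 and -0.012 after quantile normalization, neither past the threshold, and the call also ended with the genes of highest mean alone. The proteasome list of 31 genes had 15 members higher and 16 lower (adjusted p = 0.85), and passed with a median of 0.29 without mKO/Bhet replicate 3 and of 0.38 after quantile normalization.

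Published targets of the deleted microRNAs did not move as a group between mKO/Bhet and Bhet. The 14 miR-451 targets had a median log2 difference of 0.04 and a mean of -0.01 (adjusted p = 0.737), and the 11 miR-144 targets a median of -0.17 (adjusted p = 0.102). These medians were 0.18 and 0.042 without mKO/Bhet replicate 3, and the miR-144 targets passed as lower without Bhet replicate 3 (-0.51) or mKO/Bhet replicate 1 (-0.35). Ywhaz, the 14-3-3ζ gene, differed by 0.57 (SE 0.28), Cab39, a cofactor of the kinase LKB1, by 0.25 (SE 0.27) and Rab14 by 0.07 (SE 0.23), with adjusted p of 0.691, 0.816 and 0.93. The autophagy kinase gene Ulk1 differed by -0.23 (SE 0.22), Foxo3 by -0.83 (SE 0.41), Nfe2l2 by 0.29 (SE 0.24) and the autophagy receptor gene Sqstm1 by 0.14 (SE 0.29). For iron and heme, Tfrc, the transferrin receptor, differed by -1.36 (SE 0.83), Tfr2 by 0.89 (SE 0.42) and the heme enzyme gene Alas2 by -0.34 (SE 0.24). Among globins below saturation, Hbq1a differed by -1.23 (SE 0.50), Hbq1b by -0.90 (SE 0.46), Hbb-y by -0.27 (SE 0.15), Hbb-bh1 by -0.09 (SE 0.07), Hbb-bh2 by 0.15 (SE 0.09), Hba-x by 0.14 (SE 0.08) and Hbb-bh0 by 0.04 (SE 0.16). Of these Hbb-bh1, Hbb-bh2 and Hba-x lay at or below background in both groups. The sign of Hbb-bh0 and Rab14 turned when each array was centred on its median, and that of Ulk1 after quantile normalization. Without mKO/Bhet replicate 3 Foxo3 differed by -0.54, Ulk1 by -0.12, Nfe2l2 by 0.50, Sqstm1 by 0.48, Hbb-bh0 by -0.10 and Hbb-bh2 by 0.07. The Nfe2l2 difference shrank without mKO/Bhet replicate 1, whose signal of 8.83 was the highest in either group. With an array left out Cab39 ranged from 0.10 to 0.42.

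Neutrophil markers had a median log2 difference of -0.73 between mKO/Bhet and Bhet (adjusted p = 9.2e-06, or 0.554 with an estimated correlation). The signs of the 3 saturated members follow the ceiling of each array, and the 14 others, 12 of them lower, had a median of -0.86 (adjusted p = 8.4e-06, or 0.554 with an estimated correlation), for example Mmp8 at -1.54 (SE 0.60) and Ltf at -0.85 (SE 0.33). Without mKO/Bhet replicate 3 these medians were -0.04 and -0.15, Mmp8 differed by -0.67 and Ltf by -0.34, and the list did not pass. Monocyte and macrophage markers had a median of -0.23 (adjusted p = 0.00702) and mast cell, basophil and eosinophil markers one of -0.38 (adjusted p = 0.00904), each at 0.554 with an estimated correlation. T and NK cell markers had a median of -0.16 (adjusted p = 0.0227, or 0.554 with an estimated correlation). Cell cycle genes had one of -0.22 (adjusted p = 0.00085, or 0.554 with an estimated correlation) and early progenitor genes one of -0.36 (adjusted p = 0.00323, or 0.537 with an estimated correlation). These 5 lists did not pass without mKO/Bhet replicate 3, with medians of -0.0016 for monocyte, 0.12 for mast cell and -0.031 for T and NK cell markers, 0.082 for cell cycle and -0.12 for early progenitor genes. None of the 5 passed after quantile normalization, only the early progenitor list passed with the genes of highest mean alone or with centred arrays, and T and NK cell markers did not without Bhet replicate 2 (-0.067) or mKO/Bhet replicate 2 (-0.095). The cell cycle median was -0.068 without Bhet replicate 3. The 17 monocyte and macrophage markers below saturation had a median of -0.25, which was -0.57 without mKO/Bhet replicate 1. B cell markers had 12 of 14 members higher and a median of 0.36 that did not pass (adjusted p = 0.102), with Cd79b at 1.41 (SE 0.71) and Cd79a at 1.33 (SE 0.69). These genes were at 0.83 and 0.66 without Bhet replicate 3 and at 2.17 and 2.10 without Bhet replicate 2. The list median was 0.097 and 1.09 in the same cases and 0.92 without mKO/Bhet replicate 3, passing in the latter 2, and it was 0.0014 without mKO/Bhet replicate 1.

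**Figure D3:**
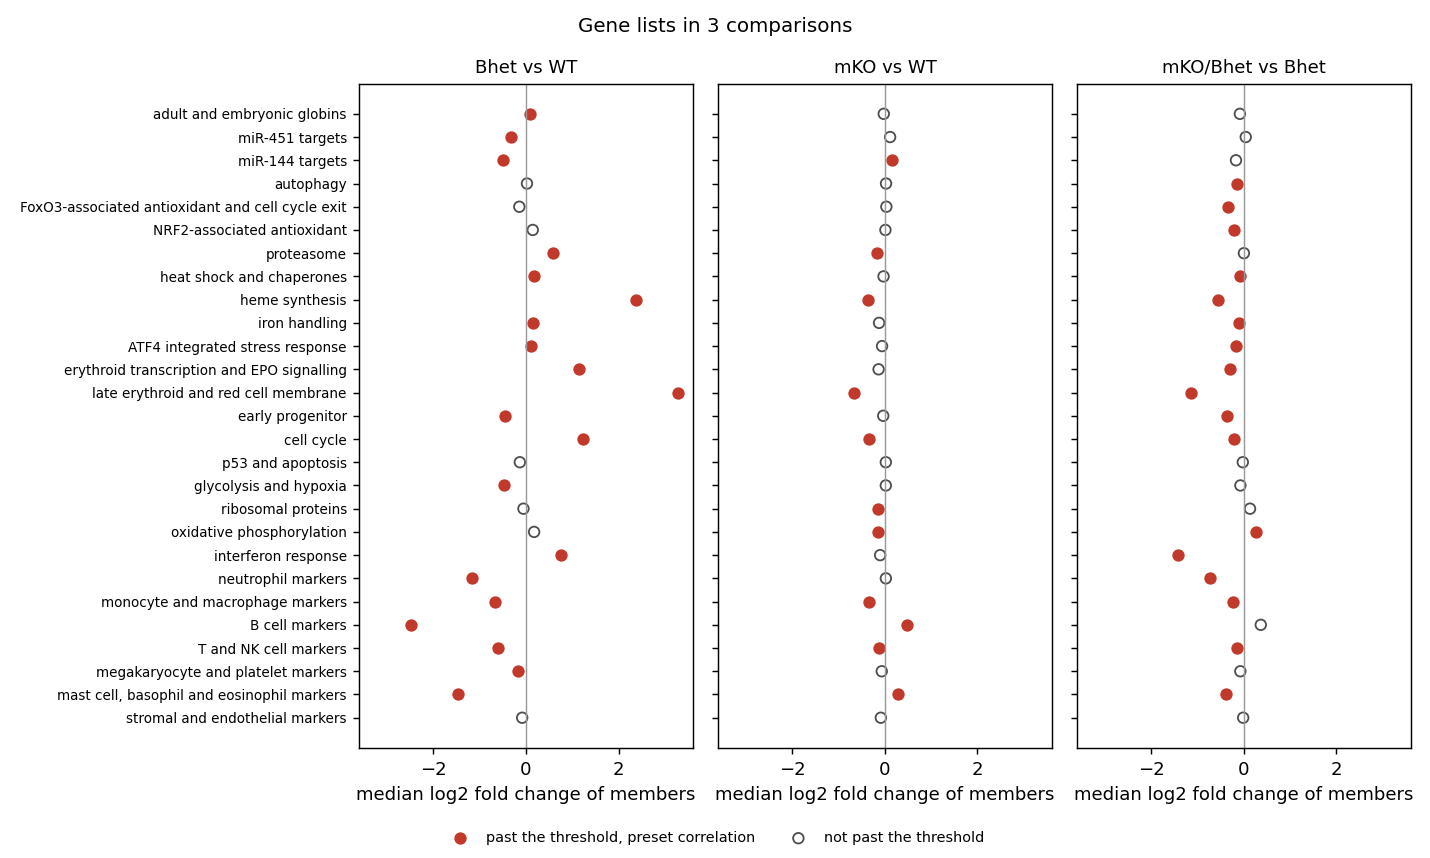
Median log2 fold change of the members (horizontal axes) of each of 27 gene lists (vertical axis) in 3 comparisons. Filled points passed camera's test with the preset correlation and open points did not, and late erythroid genes had medians of 3.29 for Bhet against WT, -0.67 for mKO against WT and -1.14 for mKO/Bhet against Bhet.

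Bhet against WT asks what the thalassemic genotype changes where the microRNAs are present. Plek2, a pleckstrin family gene, rose by 5.80 on the log2 scale (SE 0.85, adjusted p = 0.0254), Erfe by at least 3.59 against the WT background (measured 4.66, SE 0.47, adjusted p = 0.00775) and the apolipoprotein L genes Apol11b and Apol11a by 4.58 (SE 0.55) and 3.95 (SE 0.63). Other large rises were those of Add2, which encodes the membrane skeleton protein β-adducin, at 4.10 (SE 0.75), Tmcc2 at 3.74 (SE 0.56), Trim10 at 3.72 (SE 0.77), Rnf123 at 3.63 (SE 0.63), the porphyrin transporter gene Abcg2 at 3.57 (SE 0.72) and Isg15 at 3.55 (SE 0.62). Among the genes that fell, log2 changes were -2.35 (SE 0.48) for the peptidoglycan receptor gene Pglyrp1, -1.78 (SE 0.31) for Gpr84 (a fall of at least 1.14 against the Bhet background), -1.71 (SE 0.29) for Clec4b2, -1.69 (SE 0.34) for Clec12a, -2.01 (SE 0.40) for Pilrb2 and -1.78 (SE 0.34) for Pilrb1. Tmem50b at -2.20 (SE 0.39), Cyrib at -1.87 (SE 0.38), Slc50a1 at -1.83 (SE 0.35) and Sptlc2 at -1.68 (SE 0.33) also fell. In limma's test 283 genes changed, 210 higher and 73 lower, 193 of them at least 2-fold. In 75 of them, 61 higher, the dimmer group lay at or below background on every array, so their changes are uncertain, and in 47 both groups did. The groups did not overlap for 24.8% of genes, where chance gives 10%. The count rested on single arrays: it was 0 without WT replicate 2 or WT replicate 3, 6, 25 and 31 without Bhet replicates 1, 2 and 3, and 37 and 96 without mKO replicates 1 and 2. It was 2041 (707 higher and 1334 lower) without WT replicate 1, 1765 (791 higher and 974 lower) without mKO/Bhet replicate 3, and 861 (431 higher and 430 lower) among the 15489 genes of highest mean, so the balance of directions is not settled. It was 684 (416 higher) after quantile normalization, 6 (all higher) with arrays centred on their medians, and 0 with the mean of Y-linked genes or of late erythroid genes as a covariate. Only Bhet replicate 2 shared the high Y-linked signal of the WT arrays, so sex is largely confounded with this comparison.

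Late erythroid and red cell membrane genes had a median log2 change of 3.29, with 23 of 24 higher, 4 past the threshold over all genes and 18 when adjusted over the list alone. Among those past it over all genes were Add2, Icam4 at 2.31 (SE 0.38) and Trim58 at 2.12 (SE 0.40). Heme synthesis genes had a median of 2.37, with 1 of 15 past the threshold and 12 higher when adjusted over the list alone, and Ppox at 2.85 (SE 0.62) and Urod at 2.64 (SE 0.62) did not pass over all genes. In the erythroid transcription and EPO signalling list, with a median of 1.15, 4 of 19 genes rose: Cish by at least 2.81 (measured 3.43, SE 0.34, adjusted p = 0.00775), Pim1 by 3.42 (SE 0.67), Tal1 by 3.38 (SE 0.64) and Nfe2 by 1.64 (SE 0.31). All 30 cell cycle genes were higher, with a median of 1.24 and 21 past the threshold when adjusted over the list alone, and Birc5, which encodes survivin, passed over all genes at 1.85 (SE 0.38). The adjusted p with the preset correlation was 4.1e-15, 1.5e-07, 3.7e-05 and 1.3e-13 for these lists, and 0.274, 0.299, 0.274 and 0.299 with an estimated correlation. Proteasome genes had a median of 0.58, with 27 of 31 higher and none past the threshold (adjusted p = 0.00013, or 0.483 with an estimated correlation), and 0.36 without Bhet replicate 3.

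In the ATF4 list 1 of 23 genes rose, as did 2 of 17 NRF2-associated genes, 2 of 13 heat shock and chaperone genes, 2 of 19 FoxO3-associated genes and 2 of 13 iron handling genes, and none fell. The lists had medians of 0.12, 0.15, 0.18, -0.14 and 0.15, with adjusted p of 0.0154, 0.324, 0.00785, 0.409 and 0.013, and of 0.382, 0.751, 0.382, 0.792 and 0.411 with an estimated correlation. The ATF4 call ended without Bhet replicate 2 and the heat shock call without WT replicate 1. Quantile normalization gave medians of 0.21 for NRF2, 0.38 for heat shock and 0.28 for iron handling, and the NRF2 list then passed. Centred arrays gave 0.024 for ATF4, 0.053 for NRF2, 0.088 for heat shock, -0.24 for FoxO3 and 0.056 for iron handling. Without Bhet replicate 3 the medians were 0.18 for ATF4, 0.032 for NRF2, 0.0077 for FoxO3 and 0.23 for iron handling. Without Bhet replicate 1 those of NRF2 and iron handling were each 0.073. Ppp1r15a rose by 3.23 (SE 0.43, adjusted p = 0.0202), Nqo1, an NRF2 target, by 2.95 (SE 0.59), Hspa1a by at least 1.02 (measured 2.76, SE 0.48), Hspa1b by at least 1.84 (measured 2.30, SE 0.41), Srxn1 by 2.05 (SE 0.34), Foxo3 by 2.01 (SE 0.41) and Gadd45a by 1.28 (SE 0.22). The autophagy genes Atg4d and Ulk1 rose by 2.37 (SE 0.47) and 1.11 (SE 0.22), while their list of 36 had a median of 0.02 (adjusted p = 0.893). The iron importer gene Slc11a2 rose by 1.99 (SE 0.39) and the hexokinase gene Hk1 by 1.86 (SE 0.37). Tfrc at 3.10 (SE 0.83, adjusted p = 0.0882), Klf1 at 3.92 (SE 1.17, adjusted p = 0.115), Bcl2l1 at 0.96 (SE 0.23, adjusted p = 0.0715) and Alas2 at 0.33 (SE 0.24) did not pass, and Klf1, Tfrc and Alas2 turned negative with the late erythroid mean as a covariate. Alas2 was at 0.11 without WT replicate 2. Klf1 and Bcl2l1 were chosen for this comparison after their values were seen. The miR-451 targets had a median of -0.32 (adjusted p = 0.0135, or 0.411 with an estimated correlation), with Ywhaz at -0.94 (SE 0.28) and Cab39 at -0.77 (SE 0.27), neither past the threshold, and the miR-144 targets one of -0.50 (adjusted p = 0.000905, or 0.382 with an estimated correlation). The miR-451 target call ended without WT replicate 3 (-0.26), without Bhet replicate 3 (-0.21) and after quantile normalization (-0.19), with centred arrays (-0.42) and with the genes of highest mean alone (-0.34), and the miR-144 target call with those genes (-0.50). Interferon genes had a median of 0.75 (adjusted p = 0.013, or 0.591 with an estimated correlation), which was -0.087 without Bhet replicate 3, and their call also ended without WT replicate 1 or mKO/Bhet replicate 3.

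White cell markers were lower in Bhet than in WT beside these erythroid shifts. A different mix of cells in the fractions and changes within cells cannot be told apart here. B cell markers had a median log2 change of -2.48 with 13 of 14 lower, for example Cd79b at -3.34 (SE 0.71) and Cd79a at -3.17 (SE 0.69), neither past the threshold over all genes. Mast cell, basophil and eosinophil markers had a median of -1.46, where the Fc receptor gene Ms4a2 fell by 1.45 (SE 0.28), and the proteases Mcpt8 at -2.28 (SE 0.49) and Cpa3 at -4.02 (SE 0.93) did not pass. Neutrophil markers had a median of -1.16 with none past the threshold, and the 14 below saturation, all lower, had one of -1.40 (adjusted p = 1.5e-06, or 0.341 with an estimated correlation), including Ly6g at -2.32 (SE 0.59) and Cxcr2 at -1.77 (SE 0.54). The adjusted p with the preset correlation was 4.7e-10, 2.1e-06 and 7.1e-06 for these lists, and 0.274, 0.274 and 0.382 with an estimated correlation. T and NK cell markers had a median of -0.60 (adjusted p = 3.7e-07, or 0.274 with an estimated correlation) and monocyte and macrophage markers one of -0.68 (adjusted p = 1.45e-05, or 0.334 with an estimated correlation), which was -0.28 without WT replicate 3.

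mKO against WT asks what loss of the microRNAs changes where globin genes are normal. The inflammasome genes Nlrp1a and Nlrp1b, neighbours on chromosome 11 at 71091197 to 71144704 and 71153102 to 71230733, had log2 differences of -0.92 (SE 0.12, adjusted p = 0.203) and 0.66 (SE 0.10, adjusted p = 0.344), at signals about the background limit. Rsad2 differed by -2.82 (SE 0.68), Cdr2 by -2.24 (SE 0.59) and Bcl2l1 by -0.96 (SE 0.23). The antibody segment genes Ighv8-14 and Ighv8-4 differed by 1.46 (SE 0.43) and 0.97 (SE 0.22), Mir669j by 0.70 (SE 0.18) and Bend3 by 0.27 (SE 0.08), while Erfe differed by 0.10 (SE 0.47). Erfe and Bend3 lay at or below background in both groups. No gene passed limma's test at an adjusted p of 0.05, 253 had an unadjusted p under 0.05 against 1549 expected by chance, and the lowest adjusted p was 0.203. The groups did not overlap for 5.83% of genes, where chance gives 10%. The count was 7 with array weights and 1 without WT replicate 1.

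Late erythroid genes had a median log2 difference of -0.67 between mKO and WT, with 22 of 24 lower, including Trim10 at -1.99 (SE 0.77) and Bpgm, the 2,3-bisphosphoglycerate enzyme of red cells, at -1.06 (SE 0.38). Cell cycle genes had a median of -0.35 with 28 of 30 lower, such as Rrm2 at -0.83 (SE 0.56), and monocyte and macrophage markers one of -0.34 with 15 of 18 lower, such as Spic at -0.76 (SE 0.34). B cell markers had a median of 0.47 with all 14 higher, and the miR-144 targets one of 0.15 with 10 of 11 higher, such as Mtor at 0.43 (SE 0.26). The adjusted p with the preset correlation was 2.5e-06, 3.7e-05, 5.3e-05, 0.000523 and 0.0141 for these lists, and 0.825 for each with an estimated correlation. Without WT replicate 1 the B cell median turned to -0.11, that of the miR-144 targets to -0.043 and that of cell cycle genes was -0.052. That array also carried much of the late erythroid median (-0.23 without it), of Rrm2 (-0.36) and of Mtor (0.18), and WT replicate 3 much of Spic (-0.32 without it). Without WT replicate 2 the 5 medians were -1.49, -0.69, -0.57, 0.86 and 0.35, in the order above, and without mKO replicate 3 the late erythroid median was -1.44, that of cell cycle genes -0.62, of monocyte markers -0.22 and of B cell markers 0.31. The late erythroid call ended without WT replicate 3 (median -0.43) or mKO replicate 2 (-0.25), with -0.36 without mKO replicate 1. The cell cycle call ended without WT replicate 1, mKO replicate 1 (-0.23) or mKO replicate 2 (-0.18). The monocyte call ended without WT replicate 3 (-0.14), and the miR-144 target call without mKO replicate 1 (0.20) or 2 (0.19) and with centred arrays (0.17). The miR-451 targets had a median of 0.11 (adjusted p = 0.166), and of 0.0033 without WT replicate 1.

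The thalassemic genotype without the microRNAs was read from mKO/Bhet against mKO. The genes that rose most were Cldn13 at 5.16 (SE 1.10), Tspan33 at 4.50 (SE 0.94), the Rhesus antigen gene Rhd at 4.46 (SE 1.03), Mgst3 at 4.45 (SE 0.98), Slc38a5 at 4.27 (SE 1.04). Further rises were those of the erythroid transcription factor gene Klf1 at 4.25 (SE 1.17), Tac2 at 4.05 (SE 0.71), the water channel gene Aqp1 at 4.04 (SE 0.95), Odc1 at 4.0 (SE 0.77) and Rhag at 3.98 (SE 1.08). The genes that fell most had log2 changes of -5.41 (SE 0.93) for Bin2, -5.12 (SE 1.18) for the antibody gene Igkv6-25, -4.85 (SE 0.93) for another gene of its family, -4.73 (SE 0.93) for Cpa3, and -4.73 (SE 0.84) for Ly96. Further falls had log2 changes of -4.70 (SE 0.94) for Lilr4b, -4.55 (SE 0.75) for Lilrb4a, -4.47 (SE 0.73) for Ifi209, -4.46 (SE 0.88) for Slfn4 and -4.28 (SE 0.77) for Csf2ra. Of 24 late erythroid genes 13 rose, and 14 of 30 cell cycle genes did, while 7 of 10 mast cell, basophil and eosinophil markers and 6 of 14 B cell markers fell, with medians of 2.78, 1.46, -2.08 and -2.25. These lists had adjusted p of 0.465, 0.465, 0.429 and 0.429 with an estimated correlation. In limma's test 4031 genes changed, 1404 higher and 2627 lower, or 34.8% higher, which became 52.8% of 5068 after quantile normalization, 11.2% of 3286 with centred arrays, 49.4% of 4093 without mKO/Bhet replicate 3 and 58.3% of 11688 with array weights. In 1018 of the 4031 genes, 756 of them higher, the dimmer group lay at or below background on every array. In 666 both groups did, and all these changes are uncertain. The median log2 change of all genes went from 0.15 to 0.022 after quantile normalization and to -0.061 with centred arrays. The count was 0 without mKO replicate 1, 717 without mKO replicate 2, and 0 with the Y-linked or the late erythroid mean as a covariate. No mKO/Bhet array had the high Y-linked signal of mKO replicates 1 and 2, so sex is partly confounded with this comparison.

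mKO/Bhet against WT measured how far the double mutant lay from wild type. Tac2 rose by 4.89 (SE 0.71), Cldn13 by 4.10 (SE 1.10), Tspan8 by 3.63 (SE 0.74), the mitochondrial heme-related transporter gene Abcb10 by 3.6 (SE 0.83), and Plek2 by 3.53 (SE 0.85). Gstm5 rose by 3.46 (SE 0.62), Suox by 3.30 (SE 0.63), Slc22a23 by 3.29 (SE 0.66), Tmem14c, needed for heme synthesis, by 3.21 (SE 0.79) and Apol11b by 3.14 (SE 0.55). The genes that fell most had changes of -4.78 (SE 0.93) for Cpa3, -4.27 (SE 0.93) for Bin2, -4.26 (SE 0.96) for Stfa2l1, -4.20 (SE 0.64) for Clec5a, and -4.07 (SE 0.63) for Igsf6. The change was -4.04 (SE 0.75) for Lilrb4a, -3.86 (SE 0.84) for Ly96, -3.82 (SE 0.94) for Lilr4b, -3.79 (SE 0.68) for the leukocyte antigen gene Ptprc and -3.76 (SE 0.88) for Slfn4. Late erythroid, neutrophil and mast cell lists had medians of 1.68, -1.51 and -1.79, with 1, 7 and 6 members past the threshold, and adjusted p of 0.6, 0.485 and 0.394 with an estimated correlation. The medians were 0.73 for late erythroid genes without WT replicate 2 and -0.69 for neutrophil markers without mKO/Bhet replicate 3, or -1.70 and -0.98 for the 14 neutrophil markers below saturation with and without that array. In limma's test 2018 genes changed, 461 higher and 1557 lower, or 22.8% higher, which became 46.2% of 2718 after quantile normalization, 7.81% of 1524 with centred arrays, 48.2% of 1625 without mKO/Bhet replicate 3 and 62.2% of 13581 with array weights. The count was 0 without WT replicate 2, 1 without WT replicate 3, 1207 without Bhet replicate 1, 1343 without mKO/Bhet replicate 1, 4150 without WT replicate 1, 2 with these groups alone in the fit, and 0 with the Y-linked or the late erythroid mean as a covariate. In 347 of the 2018 genes, 241 of them higher, the dimmer group lay at or below background on every array. In 175 both groups did, and all these changes are uncertain. Y-linked means were 6.71 to 7.42 on the WT arrays and 4.35 to 4.81 on the mKO/Bhet arrays. Sex and genotype thus cannot be told apart here.

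Averaged over both microRNA genotypes, log2 signal was higher in the thalassemic groups by 4.87 (SE 0.60) for Plek2, 4.82 (SE 0.78) for Cldn13, 4.22 (SE 0.66) for Tspan33, 4.19 (SE 0.73) for Rhd and 4.08 (SE 0.83) for Klf1. On the other side the log2 changes were -4.38 (SE 0.66) for Cpa3, -3.70 (SE 0.66) for Bin2, -3.68 (SE 0.59) for Ly96, -3.45 (SE 0.44) for Igsf6 and -3.43 (SE 0.68) for Stfa2l1. In limma's test 6328 genes changed, 2691 higher and 3637 lower, or 42.5% higher, which became 17.8% of 5177 with centred arrays, 48.1% of 6276 after quantile normalization, 59.7% of 11825 without the 2 outlying arrays (WT replicate 1 and mKO/Bhet replicate 3) and 63.7% of 17816 with array weights. The balance of directions is thus not settled. The count was 3978, 4199 and 4053 without WT replicate 2, WT replicate 3 and mKO replicate 1, and 0 with the Y-linked or the late erythroid mean as a covariate. Y-linked signal was high on all WT arrays and mKO replicates 1 and 2, and among thalassemic arrays on Bhet replicate 2 alone. Sex is thus largely confounded with the thalassemic genotype, and the Y-linked covariate cannot tell them apart. List means of late erythroid genes were 11.32 in WT and 10.60 in mKO against 14.01 in Bhet and 12.94 in mKO/Bhet. Those of neutrophil markers were 17.36 and 17.30 against 16.29 and 15.66, in the same order. A different mix of erythroid and white cells thus cannot be told apart from changes within cells. The late erythroid covariate, which itself differs between the groups, cannot separate them. The changes of Bhet against WT and of mKO/Bhet against mKO, which share no arrays, correlated across genes at r = 0.748 (rho = 0.654, genes being no independent replicates). Of the 283 genes changed in Bhet against WT, 279 had the same sign in the other comparison. The calls shared 106 higher genes, where independent lists would share 9.52, and 64 lower genes, where they would share 6.19. Both calls used the same estimate of each gene's spread, and mean Y-linked signal was lower in the thalassemic group of both comparisons. The overlap is therefore no independent test of the genotype.

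Averaged over both globin genotypes, loss of the microRNAs gave log2 differences of -3.24 (SE 0.48) for Rsad2, -1.67 (SE 0.24) for Slc2a4, -1.27 (SE 0.16) for Bcl2l1, -0.64 (SE 0.08) for Nlrp1a and -0.52 (SE 0.07) for Apold1. It gave differences of 2.17 (SE 0.50) for Tac2, 1.08 (SE 0.24) for H2az2, 0.71 (SE 0.15) for Bex4, 0.44 (SE 0.07) for Nlrp1b and 0.34 (SE 0.06) for Mex3d. None passed limma's test, where 0 genes changed, 837 had an unadjusted p under 0.05 and the lowest adjusted p was 0.118. The count was 1274 with array weights. The difference of the microRNA effect between globin genotypes, tested as an interaction, was -3.50 (SE 0.67) for Erfe, -2.53 (SE 0.50) for Ighg1, -1.63 (SE 0.34) for Tbxas1, -1.56 (SE 0.28) for H1f3 and -0.69 (SE 0.14) for Agrn. It was 2.19 (SE 0.52) for Atp5g2, 1.93 (SE 0.47) for H2az2, 1.13 (SE 0.28) for Sh2d4a, 0.79 (SE 0.20) for Mir3068 and 0.59 (SE 0.12) for Mex3d. Here too 0 genes passed, 1324 had an unadjusted p under 0.05 and the lowest adjusted p was 0.894, with 1074 passing under array weights. Across all genes the microRNA effects in the 2 globin genotypes correlated at r = -0.271 (rho = -0.203), which became 0.097 without WT replicate 1.

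Most genes raised in Bhet were closer to their WT level in mKO/Bhet. Of the 210 genes higher in Bhet than WT, 206 were lower in mKO/Bhet than in Bhet, while of the 73 lower genes 22 were higher in mKO/Bhet. Together 228 of 283, or 80.6%, had the opposite sign, against 67.5% in simulations where mKO/Bhet equalled Bhet and the Bhet arrays were shared, and the median change back was 41.4% of the change in Bhet, against 11.7% simulated. The simulated share covers both directions together, so the 206 of 210 genes, picked for high Bhet values, have no baseline of their own. None of the 283 passed the threshold between mKO/Bhet and Bhet, and 123 of them passed it between mKO/Bhet and WT. Under other settings the share of opposite signs covers the genes called there. It was 41.8% of 2041 genes without WT replicate 1 and 60.6% of 861 among the 15489 genes of highest mean signal. It was 100% of 6 genes without Bhet replicate 1 and 100% of 31 without Bhet replicate 3. It was 68.6% after quantile normalization and 67.9% without mKO/Bhet replicate 3, and no such simulation was made for these settings. Over all genes the covariance of the changes was -0.0065 against -0.0358 simulated from the shared Bhet arrays, so no return was seen across the whole set.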

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

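The tests of the 3 patterns weighed here were chosen only after the results were seen, while the counts of other splits and the interaction were planned.

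The interaction of the microRNA and globin genotypes passed for 13 of 27 lists with the preset correlation and for 0 with an estimated correlation, where the lowest adjusted p was 0.676. The interferon list had a median difference in log2 change between the globin genotypes of -1.20, mast cell, basophil and eosinophil markers one of -0.71, late erythroid genes -0.50, miR-144 targets -0.45, FoxO3-associated genes -0.43, neutrophil markers -0.35 (-0.83 for the 14 below saturation) and early progenitor genes -0.30. Heat shock genes had -0.16, autophagy genes -0.12, NRF2-associated genes -0.098 and erythroid transcription and EPO signalling genes -0.087. Oxidative phosphorylation genes had 0.46 and ribosomal protein genes 0.29. Single arrays carried much of this: without mKO/Bhet replicate 3 the 13 lists (2 higher, 11 lower) became 4 (3 higher, 1 lower), and 10 of the 13 lost their call, with -0.18 for mast cell and -0.0049 for neutrophil markers. The interferon median was -0.53 without Bhet replicate 3, and that of late erythroid genes 0.25 without WT replicate 2 and 0.21 without mKO replicate 3. With centred arrays 5 lists passed and after quantile normalization 6. The probe set over the region of miR-144 and miR-451, which has no symbol and so lies outside the genes tested, was higher in Bhet than in WT by 3.17 on the log2 scale (SE 0.49).

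At an adjusted p under 0.10, 10 genes were lower in mKO/Bhet than in Bhet (Agrn, Ankle1, Apold1, Bcl2l1, Erfe, H1f3, Slc2a4, Spata13, Tbxas1 and Trmo), with a median log2 difference of -1.49 and a median SE of 0.21. Without mKO/Bhet replicate 3 their median was -1.42, without Bhet replicate 2, the Bhet array with Y-linked signal, it was -1.47, and with the late erythroid mean as a covariate it was -1.34. These values exclude none of the 3 explanations, since the genes were picked on the same arrays for small differences within groups. A microRNA effect that includes Erfe and Bcl2l1 may lie behind them, but the genes were picked for being lower and none passed the threshold of 0.05, so this stays a hypothesis. Differences in cell types beyond the late erythroid mean were not tested and stay open.

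On the WT arrays the region of miR-144 and miR-451 was nearly as low as on the mKO arrays, at 5.79 ± 0.63 (SD, n = 3) against 4.80 ± 0.36. The mean background limit was 5.25 in WT and 4.96 in mKO, so these signals are dim and the rise to Bhet may be understated. Of the 24 measured late erythroid genes 13 had a larger change from WT to Bhet than the region did, in a list with a median of 3.29, a lowest value of -0.04 and a highest of 4.10, and none of its members is in another list (0). This would go with fewer erythroid cells in the WT fractions, but only a change above that of every member would have spoken against it. Slc4a1 (17.57 ± 1.22) was also abundant there, and the fractionation for erythroblasts would be meant to remove other cells. The alternative of mKO mice under the WT label stays open, since the region did not separate WT from mKO (two-sided exact permutation p = 0.2, with 0.1 the smallest possible). Bcl2l1 did separate them (8.02 to 8.43 in WT, 7.08 to 7.55 in mKO), as did Nlrp1a and Nlrp1b. These genes were picked for small p on the same arrays, so they do not settle the label.

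Nlrp1a was lower and Nlrp1b higher in mKO than in WT, neither past the threshold, and these neighbours lie 6.96 and 6.88 Mb from the locus of miR-144 and miR-451. Nlrp1a in mKO (3.90 ± 0.02) and Nlrp1b in WT (4.22 ± 0.08) lay below the background limit on every array, so the pattern rests on dim signals. The directions were the same from Bhet to mKO/Bhet, at 4.33 and 3.97 for Nlrp1a and 4.15 and 4.37 for Nlrp1b. All of these lay below the background limit. DNA of another strain kept around the locus may give such differences: of the 100 genes with the smallest p, other than this pair, 7 lay within 20 Mb of the locus, where 2.96 would by chance (exact hypergeometric p = 0.0291), with 12 of 200 (p = 0.0165) and 3 of 50 (p = 0.184). It stays open, since Bhet against WT, whose labels name no loss of this locus, gave 6 of 100 (exact hypergeometric p = 0.0766). By the same exact hypergeometric test mKO/Bhet against Bhet gave 5 of 100 (p = 0.175) but 12 of 200 (p = 0.0165). The average microRNA effect gave 10 of 100 (exact hypergeometric p = 0.000771) and 15 of 200 (p = 0.000963). For mKO/Bhet against mKO the number was 1 of 100, among 18 combinations looked at with 917 genes in the window. The requirement that all 3 list sizes pass was set after their values were seen, and Slc2a4, of the 10 genes above, is in this window too.

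With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. As many genes as the real split were given by 1 of them for Bhet against WT (283, highest other 0), 1 for mKO/Bhet against WT (2018, highest other 0) and 1 for mKO/Bhet against mKO (4031, highest other 0). A real count of 0 is met by every split, here 10 for mKO/Bhet against Bhet (highest other 1) and 10 for mKO against WT (highest other 70). Of 100 splits, 100 gave as many genes as the interaction (0, highest other 10) and 100 as many as the average microRNA effect (0, highest other 107), where a real count of 0 fixes the outcome and says nothing of chance. For the average thalassemic effect 2 of 100 splits gave as many genes as the real 6328, the highest other giving 8442. That split amounts to exchanging WT replicate 1 and Bhet replicate 2 and points to a structure of the samples. WT replicate 1 lies with the Bhet and mKO/Bhet arrays on component 1, and without it the 283 genes of Bhet against WT became 2041. Its Erfe signal of 4.31 and Foxo3 signal of 8.11 lay below every Bhet array (lowest 7.57 and 9.66). Its neutrophil marker mean of 17.38 lay above the Bhet arrays, of which replicate 2 was highest at 16.45. These values argue against a Bhet mouse under this label. Its proteasome mean of 9.86 lay between those of Bhet replicates 2 (9.72) and 1 (10.08), and its label was not checked otherwise.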

How the results depend on the processing

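The covariates, the lists without saturated members, the joint removal of the outlying arrays WT replicate 1 and mKO/Bhet replicate 3, and the removal of arrays of groups not compared were chosen only after the results were seen. Where a value below differs, the cause was not tested. Counts with array weights rest largely on single arrays of WT, Bhet and mKO/Bhet, by the weights given above. Of 4307 alternative values for 189 gene results, 3438 kept their direction and side of the threshold. Of the others 708 lost and 148 gained the threshold, and 13 turned sign. Of 1470 for 70 list results 1150 kept both, 273 lost and 10 gained the threshold and 37 turned. Many fold changes could not turn: no trend, the compared groups alone, the replicate block and removal of another group's array leave them as they were. Many gene results also came from comparisons where 0 genes passed. The shares kept are therefore no measure of how robust the results are. Tests of microRNA seed sites were not run, since no 3' UTR annotation was at hand, and the second deposited table held the same values, so it gave no alternative. Antigenomic background probes had medians of 3.21 to 3.36 on the log2 scale, which limits what can be said of dim genes.

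The numbers of the replicates were not taken to pair the arrays, whose mice have numbers of their own. Some mouse numbers recur in another group, and the deviations of those arrays correlated at 0.51 (WT replicate 2 with mKO replicate 1, the most similar arrays of all), 0.24 (Bhet replicate 1 with mKO replicate 2) and 0.04 (Bhet replicate 3 with mKO replicate 3), while the labels do not say what a shared number means. Of 18 pairs with the same number 7 correlated above 0.1, from -0.45 to 0.37, and 1 array correlated best with its own number. In Bhet and mKO/Bhet alone all 3 pairs did (0.15, 0.16 and 0.26), so pairing is not excluded there, and the block left 0 genes and 17 lists, as without it. With the replicate number as a block, 32 genes passed for Bhet against WT, 0 for mKO/Bhet against Bhet, 0 for mKO against WT, 1679 for mKO/Bhet against WT, 3333 for mKO/Bhet against mKO and 5602 for the average thalassemic effect.

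For mKO/Bhet against Bhet, 0 genes became 11 (1 higher, 10 lower) with the genes of highest mean alone and 3973 with array weights. The count was 5 after quantile normalization, 1 with centred arrays and 1 without the 2 outlying arrays. With the Y-linked covariate it was 2 and with the late erythroid covariate 1. It ranged from 0 to 3 with an array left out. For Bhet against WT, 283 genes became 861 with the genes of highest mean, 70 with each cluster on its own, 160 with the groups compared alone, 13780 with array weights, 684 after quantile normalization, 6 with centred arrays, 0 with either covariate and 5152 without the outlying arrays. It ranged from 0 to 2041 with an array left out. For mKO against WT, 0 became 7 with array weights and 1 without the outlying arrays (0 to 1 with an array left out). For mKO/Bhet against WT, 2018 became 2 with the groups compared alone, 13581 with array weights, 0 with either covariate and 5639 without the outlying arrays (0 to 4150). For mKO/Bhet against mKO, 4031 became 2623, 11688, 0 with either covariate and 6448 under the same settings (0 to 4983). For the interaction, 0 became 1074 with array weights and 1 without the outlying arrays (0 to 1). For the average microRNA effect, 0 became 1274 with array weights, 1 after quantile normalization, 2 with the late erythroid covariate and 2 without the outlying arrays (0 to 2). For the average thalassemic effect, 6328 became 17816 with array weights, 0 with either covariate and 11825 without the outlying arrays (3978 to 8467).

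With an estimated correlation 0 lists passed in every comparison. With fry, 0 passed for mKO/Bhet against Bhet (4 in the mixed test), Bhet against WT (21 mixed), mKO against WT (0 mixed), the interaction (0 mixed) and the average microRNA effect (0 mixed), 3 for mKO/Bhet against WT (21 mixed), 8 for mKO/Bhet against mKO (25 mixed) and 16 for the average thalassemic effect (25 mixed). The 17 lists of mKO/Bhet against Bhet became 8 with the genes of highest mean and 6 after quantile normalization, 3 of them higher (6 to 19 with an array left out). The 6 without mKO/Bhet replicate 3 were 4 higher and 2 lower, where the 17 were 1 higher and 16 lower, and none was higher without mKO/Bhet replicate 1 or 2. The 19 of mKO/Bhet against WT became 12 with the genes of highest mean, and the 13 of the interaction became 7 with those genes, 6 after quantile normalization and 5 with centred arrays (4 to 15, with 3 higher and 1 lower of the 4 without mKO/Bhet replicate 3). In the interaction the autophagy direction turned after quantile normalization (0.076), and the late erythroid median ranged from -0.99 to 0.25. Without saturated members 17 lists passed for mKO/Bhet against Bhet and 20 for Bhet against WT, as with them, and 12 for mKO against WT. The 11 lists of mKO against WT ranged from 4 to 12 and the 18 of the average microRNA effect from 10 to 20 with an array left out.

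Signs turned in these cases. Between mKO/Bhet and Bhet, Hbb-bh0 was -0.063 with array weights, -0.057 with centred arrays and -0.10 without the outlying arrays (-0.10 to 0.11 with an array left out), Rab14 -0.025 with centred arrays (-0.0078 to 0.20), Ulk1 0.097 after quantile normalization and Sqstm1 -0.11 to 0.48 with an array left out. The oxidative phosphorylation median ranged from 0.093 to 0.52 and the autophagy median from -0.29 to -0.016, with the test's direction turning at the value nearest 0. Iron handling ranged from -0.29 to 0.025, mast cell markers from -0.91 to 0.12 and B cell markers from 0.0014 to 1.09, the direction turning at 0.097 without Bhet replicate 3. The direction for miR-451 targets turned with fry (0.039), the genes of highest mean (0.022) and quantile normalization (0.14), and their median ranged from -0.049 to 0.18. That for miR-144 targets turned after quantile normalization (-0.12), with a range of -0.51 to 0.042. That for the proteasome turned with fry (-0.00037), the genes of highest mean (-0.00037), quantile normalization (0.38) and centred arrays (-0.094), with a range of -0.14 to 0.29. In Bhet against WT the autophagy direction turned with fry (0.021), the genes of highest mean (0.034), quantile normalization (0.12) and centred arrays (-0.072), with a range of -0.00057 to 0.15. There the FoxO3 direction turned with fry (-0.14), the genes of highest mean (-0.14) and quantile normalization (0.013), with a range of -0.21 to 0.0077, and the interferon median ranged from -0.087 to 1.32. With the late erythroid covariate Klf1 was -0.50, Alas2 -0.41 and Tfrc -0.17 in Bhet against WT, and Klf1 -0.055 in the average thalassemic effect. With the Y-linked covariate Erfe was -0.26 in mKO against WT, where B cell markers ranged from -0.11 to 0.86 and miR-144 targets from -0.043 to 0.35, and miR-451 targets from 0.0033 to 0.18. The correlation of the microRNA effects ranged from -0.36 to 0.097, and the share of genes with the opposite sign in mKO/Bhet was 60.6% with the genes of highest mean and 41.8% to 100% with an array left out.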

Other observations

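In mKO/Bhet against mKO, 5 of 31 proteasome genes and 4 of 28 oxidative phosphorylation genes rose and none of either list fell, with median log2 changes of 0.72 and 0.60 (adjusted p = 0.00077 and 0.00234 with the preset correlation, and 0.575 for each with an estimated correlation). The oxidative phosphorylation call ended without mKO/Bhet replicate 1 (median 0.53) or 2 (0.44), and the proteasome median was 0.48 without mKO/Bhet replicate 2. After quantile normalization the medians were 1.12 for the proteasome and 0.99 for oxidative phosphorylation, and the latter was 0.39 with centred arrays. Early progenitor genes had a median of -0.76, with 9 of 14 fallen and 1 risen, and the miR-144 targets one of -0.47, with 4 of 11 fallen and none risen (adjusted p = 3.1e-06 and 2.7e-05, and 0.429 for each with an estimated correlation).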
